A study of Mus musculus with 16 samples.

How the data were processed

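Gene expression was measured in heart ventricles of 129Sv mice with 16 two-colour microarrays. Wild-type mice and mice lacking CHIP (CHIP-/-), the co-chaperone and ubiquitin ligase encoded by Stub1, were studied 1 week after a sham operation or trans-aortic banding (TAB), a constriction of the aorta that raises the pressure against which the left ventricle pumps. Per the labels, each of the 4 groups held 4 biological replicates. Per the labels' protocols, total RNA was extracted with Trizol, 500 ng of heart RNA was labelled with Cy5, 500 ng of a whole mouse reference RNA from neonatal animals was labelled with Cy3, and both were amplified with a low input kit. All arrays had the same dye orientation, so a gene's dye bias is shared by the groups and leaves their differences.

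Per the file headers, the arrays carried Agilent pattern 014868, were read on a GenePix 4000B scanner, and were quantified with Feature Extraction 9.1.3.1. The deposited scanner files give, as linear intensities, the mean signal of each spot and the median of its local background in both channels. They also give Feature Extraction's processed intensities, which per the file headers were background-subtracted (method code 7) with spatial and multiplicative detrending and then dye-normalized, and a log10 ratio of the processed heart over reference intensity. In the deposited log10 ratios, 24.9% of spots were exactly 0, and 21.8% of spots held substitute values in both channels. The deposited series table gives log2 ratios of 14322 probes. Each of its columns equalled its own array's log10 ratio, turned to log2 and centred on the probe's median over the arrays, with correlations of at least 0.999. Its columns had medians from -0.03 to 0.03, and how its probes were chosen is not given in the sources used here. In the 4 CHIP-/- TAB files the mean signals were saved with 3 significant digits, against at least 7 in the others, and 47 gene names had been altered; names were therefore taken by probe identifier from the other files.

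Mean signals were corrected with limma's normexp method (offset 50) on the median local background, and log2 ratios of heart over reference were normalized within each array by loess, with control spots at weight 0. Each array held 45018 spots, of which 43379 were no controls. Spots with an outlier mark (3 to 459 per array) were left out and saturated spots were kept. Spots of a probe were averaged, which gave 41174 probes. A probe was kept if it was well above background in the heart channel on at least 4 of the 16 arrays, which left 14908. The brightest probe stood for a gene, and a value on at least 15 arrays was required, which left 11058 features with 272 single values missing; 9766 features had a gene symbol. Of the 41174 probes, 22951 were named through their accession in a RefSeq table of assembly GRCm38.p6, 6659 through their symbol and 3109 through a synonym; 8455 kept the name in the file. Among 2914 genes with several probes, probes of 24, 43, 0, 2 and 1 genes were called in opposite directions in the 5 comparisons, in the order given next; those of the interaction were Ifi27's, and those of the comparison after TAB were Klf2's and Camta1's.

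All 16 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (files were read with the data.table package, version 1.17.8), with moderated errors and an intensity trend (median prior degrees of freedom 10.2). The 5 comparisons were TAB against sham in wild type, TAB against sham in CHIP-/-, CHIP-/- against wild type after sham, the same after TAB, and the interaction, which is the TAB response in CHIP-/- minus that in wild type. Every adjusted p is limma's with Benjamini-Hochberg adjustment over all features of that comparison, and a gene is said to rise, fall or differ where it is below 0.05. Differences are log2 with their standard error (SE). Counts of list members are given over all features and adjusted over the list alone. Where 4 arrays do not overlap with 4 others, chance alone gives 2.86% of genes.

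The 32 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists, then with camera's estimated correlation and with fry, which asks whether a list's genes move on balance in one direction and does not compare them with other genes. The lists were hypertrophy markers, adult calcium handling and ion channels, extracellular matrix, fatty acid oxidation, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, AMPK subunits and energy regulators, cytosolic chaperones, endoplasmic reticulum stress, proteasome subunits, muscle ubiquitin ligases, autophagy and lysosome, oxidative stress response, immediate early genes, cell cycle, interferon response, glucocorticoid responsive genes, circadian clock, and markers of macrophages, lymphocytes, neutrophils, endothelium, smooth muscle and pericytes, fibroblasts, atria, red cells, adipocytes, skeletal muscle, nerve and glia, thymus and sex. Several genes sit in more than 1 list, such as Col1a1 and Col3a1 in the matrix and fibroblast lists.

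The model, the gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule names Stub1; the 8 largest rises and 8 largest falls with a gene symbol whose groups did not overlap (no such condition for the interaction); a fixed panel of Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn and Timp1 for surgery and of Hspa1a, Hspb1, Bag3, Prkaa1, Prkaa2, Ppargc1a, Fbxo32 and Trim63 for genotype (Hspa1b had no tested feature); and up to 4 members per list with the smallest p. A gene named in 1 comparison may be given with its values in another. Alternatives covered the processed signals, no background subtraction, median centring in place of loess, quantile scaling of average intensity, the heart channel alone, the deposited series table, other probe filters and summaries, array weights, fits on 8 arrays, the replicate number as a block, and each array left out. Chosen after seeing the data were a normexp offset of 10, sex as a term, the position on the slide as a block, and fits without 3 arrays with Y-linked signal or without 3 arrays with high Myl7.

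The fit was tested on simulated data with the means and residual spread of the 11058 real features. A log2 change of 0.5 was recovered for 84% of 100 changed genes in TAB against sham in CHIP-/-, 85% in CHIP-/- against wild type after TAB and 46% in the interaction; a change of 1 was recovered for 100%, 100% and 99%. Of 10803 unchanged genes, 15, 7 and 8 were called. A matrix list shifted by 0.3 was found by camera with adjusted p = 1.3e-22, 1.4e-17 and 1.5e-09. The simulated genes were independent of each other and carried no slide or array effect. These values therefore do not show how often calls, above all those of lists, are false in the real arrays.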

Results

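The arrays compared ventricles of wild-type and CHIP-/- mice 1 week after sham surgery or TAB, with 4 arrays in each of the 4 groups. Each value is a log2 ratio of heart RNA over a reference RNA from whole neonatal mice, so levels of different genes are not set against each other. In the heart channel 27.0% to 37.7% of spots were well above background, and in the reference channel 56.6% to 62.4%. The median heart spot had a mean signal of 48.7 to 54.6 over a local background of 38 to 41. The number of arrays limits the precision. The arrays came from 4 slides, and each slide held exactly 1 group, so slide and group cannot be told apart in any comparison. Across genes, arrays of a group correlated at 0.956 to 0.982, against 0.844 for the least alike pair of all arrays, and the first principal component held 61.3% of the variance. Transcripts of the Y-linked genes Ddx3y and Eif2s3y were well above background on 3 sham arrays (wild-type sham replicate 4 and CHIP-/- sham replicates 2 and 4) and on none of the 8 TAB arrays. Xist was below that level on those 3 arrays only. Myl7, the atrial myosin light chain, was high on 3 other sham arrays: 3.82 and 1.89 on wild-type sham replicates 1 and 3 and 2.22 on CHIP-/- sham replicate 1, against -1.99 to 0.17 on the other 13 arrays.

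Stub1, the disrupted gene, was lower on every CHIP-/- array than on every wild-type array. Its log2 ratios were 0.30, 0.37, 0.39 and 0.44 in wild-type sham, 0.25, 0.06, -0.41 and 0.14 in wild-type TAB, -1.36, -1.31, -1.39 and -1.24 in CHIP-/- sham, and -1.47, -1.17, -1.36 and -1.29 in CHIP-/- TAB. The difference between CHIP-/- and wild type was -1.70 after sham (SE 0.10, adjusted p = 1.8e-10) and -1.34 after TAB (SE 0.10, adjusted p = 2.6e-08). Where the probe lies relative to the deleted part of the gene is not given in the sources used here. In wild type, Stub1 fell by 0.36 with TAB (SE 0.10, adjusted p = 0.0053), by 0.22 without wild-type TAB replicate 3 and by 0.72 with median centring in place of loess. In CHIP-/- the difference with TAB was 0.00 (adjusted p = 0.99) and turned to -0.37 with median centring. The interaction did not pass (0.37, SE 0.14, adjusted p = 0.14).

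**Figure D1:**
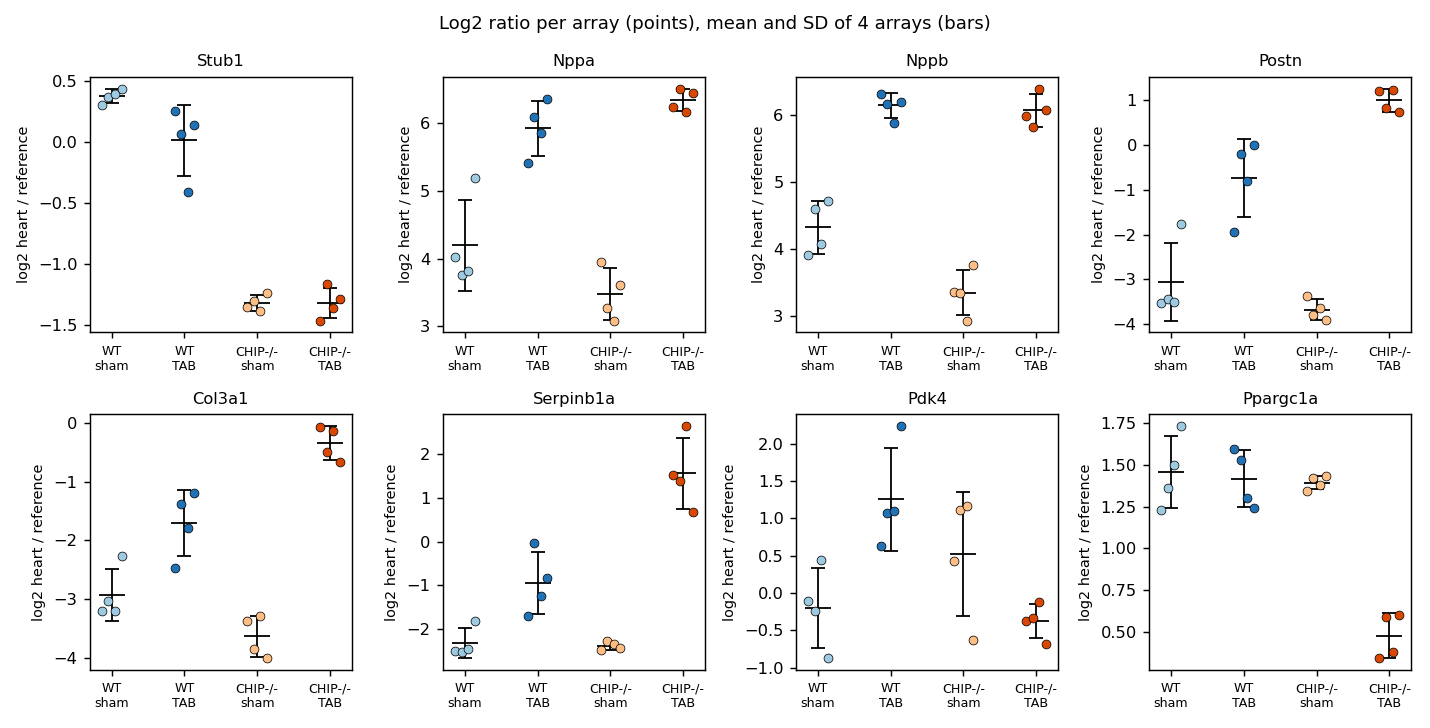
Log2 ratio of heart over reference RNA (vertical axis) for Stub1, Nppa, Nppb, Postn, Col3a1, Serpinb1a, Pdk4 and Ppargc1a, with 1 point per array, grouped by genotype and surgery (horizontal axis), and bars for the group mean and SD (n = 4). Stub1 lay between -1.47 and -1.17 on the CHIP-/- arrays and between -0.41 and 0.44 on the wild-type arrays.

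TAB against sham in wild type asks which ventricular transcripts respond to pressure overload when CHIP is present. Transcripts of the natriuretic peptides, which stretched heart muscle secretes, rose: Nppb from a mean log2 ratio of 4.32 ± 0.39 (SD, n = 4) to 6.15 ± 0.18 (n = 4), by 1.82 (SE 0.16, adjusted p = 3e-08), and Nppa by 1.73 (SE 0.23, adjusted p = 5.3e-06). Myh7, the slow beta myosin heavy chain, rose by 1.60 (SE 0.33), and Acta1, skeletal alpha actin, by 1.38 (SE 0.11). Myh6, the alpha myosin heavy chain of adult ventricle, fell by 0.48 (SE 0.08) and Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.49 (SE 0.09; its 3 probes all passed, from -1.45 to -0.49). Postn, encoding the matrix protein periostin, rose by 2.31 (SE 0.33, adjusted p = 1.2e-05), Timp1, a metalloproteinase inhibitor, by 1.58 (its 3 probes all passed, from 0.58 to 1.58) and the collagen gene Col3a1 by 1.22. The sham and TAB groups overlapped for Postn, Myh7, Col3a1 and the collagen gene Col1a1. Wild-type sham replicate 4 had -1.75, 0.56, -2.27 and -3.12 for these genes. Wild-type TAB replicate 1 lay lower, at -1.94, 0.21, -2.46 and -3.14. The largest rise was that of Nmrk2, a nicotinamide riboside kinase of NAD synthesis, by 2.84 (SE 0.26, adjusted p = 3.7e-08). Mt2, a metallothionein, Cnn1, encoding the actin-binding protein calponin, Mgp, an inhibitor of calcification, and Synpo2l rose by 1.88, 1.67, 1.64 and 1.59. Synpo2l has a second probe, which was at 0.11 and did not pass, and so has Col1a1, at 0.14. The largest falls were those of Rnf207, Ano10, Gdap10 and Asb15, by 1.64, 1.63, 1.56 and 1.35, followed by Mid1ip1, Crhr2, Ift81 and the anion exchanger Slc4a3, by 1.29, 1.26, 1.20 and 1.11. The other probes of Asb15 and Slc4a3 passed at -0.64 and -0.72. Rnf207 was well above background on only 3 of the 4 TAB arrays, so background limits the exact size of its fall and its place in this order.

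Of the hypertrophy markers, 17 of 20 measured members rose in wild type (18 adjusted over the list alone, median 0.85), among them Tagln by 1.36 and Uck2 by 1.31. Of the calcium handling and ion channel genes, 17 of 20 fell (18 adjusted over the list alone, median -0.49), with Pln, the phospholamban gene, down by 0.86 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 0.98. In the camera test the adjusted p values were 7.4e-11 and 3.2e-09, and for both adjusted p = 0.126 with an estimated correlation. Extracellular matrix genes rose in 46 of 55 cases (46 adjusted over the list alone, median 0.60), with Sparc up by 0.95 and Serpinh1, a collagen chaperone, by 0.89. The camera test gave adjusted p = 6.1e-13, and adjusted p = 0.249 with an estimated correlation. Fibroblast markers rose in 9 of 15 cases and fell in 2 (9 and 2 adjusted over the list alone), with Vim, a mesenchymal intermediate filament, up by 1.45. For this list camera gave adjusted p = 0.0024, and adjusted p = 0.249 with an estimated correlation. Macrophage and monocyte markers rose in 17 of 21 cases (18 adjusted over the list alone, median 0.42), led by the lysozyme genes Lyz2 (0.94) and Lyz1 (0.81). In the camera test it had adjusted p = 7e-08, and adjusted p = 0.202 with an estimated correlation. Endothelial markers rose in 11 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone), with the tight junction gene Cldn5 up by 0.83. By camera the list had adjusted p = 0.00056, and adjusted p = 0.264 with an estimated correlation. Smooth muscle and pericyte markers rose in 10 of 13 cases and fell in 2 (10 and 2 adjusted over the list alone). Camera returned adjusted p = 0.0039, and adjusted p = 0.202 with an estimated correlation. The medians of fibroblast, endothelial and smooth muscle markers were 0.44, 0.31 and 0.35. Over 32 other settings they ranged from 0.14 to 0.56, 0.04 to 0.41 and 0.08 to 0.51. Those of matrix genes and macrophage markers ranged from 0.26 to 0.75 and 0.17 to 0.82. At the preset correlation, camera's calls of these lists were kept in each of these settings.

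Genes of fatty acid oxidation fell in 25 of 31 cases in wild type and rose in 1 (25 and 1 adjusted over the list alone, median -0.52). Acadm, a medium-chain dehydrogenase, fell by 0.83, Etfa by 0.65 and Slc25a20, the carnitine carrier, by 0.75. The member that rose was Pdk4, a kinase that inhibits pyruvate dehydrogenase, by 1.45. Tricarboxylic acid cycle genes fell in 18 of 18 cases (18 adjusted over the list alone, median -0.45), with Sdha down by 0.69 and Pdha1 by 0.59. Camera gave adjusted p = 5e-11 and 3.2e-11 for these lists, and adjusted p = 0.235 and 0.202 with an estimated correlation. AMPK subunits and energy regulators fell in 13 of 26 cases and rose in 2 (the same numbers adjusted over the list alone), with Ppargc1b, a coactivator of mitochondrial genes, down by 0.49. This list had a camera adjusted p = 0.0014, and adjusted p = 0.126 with an estimated correlation. Oxidative phosphorylation genes went both ways: 9 of 59 rose and 11 fell (9 and 11 adjusted over the list alone), the median was 0.04, the mean -0.02 and the test pointed down, with a camera adjusted p of 0.711. Of the glycolysis genes 2 of 20 rose and 8 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0752).

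In the endoplasmic reticulum stress list 10 of 24 members rose and 2 fell in wild type (10 and 2 adjusted over the list alone), with the disulphide isomerase gene Pdia3 up by 0.48. The camera test gave adjusted p = 0.02, and adjusted p = 0.249 with an estimated correlation; the call ended with median centring (median -0.06). Cytosolic chaperones fell in 10 of 38 cases and rose in 3 (10 and 3 adjusted over the list alone), with the co-chaperone genes Fkbp4 and Bag3 down by 0.77 and 0.31. For this list camera gave adjusted p = 0.035, and adjusted p = 0.579 with an estimated correlation, a call that 8 of 32 other settings ended. Among muscle ubiquitin ligases, Trim63 and Fbxo32, which encode MuRF1 and atrogin-1, fell by 0.61 each, within 4 of 17 that fell and 1 that rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.0998). Proteasome subunits rose in 3 of 33 cases and fell in 3 (2 and 3 adjusted over the list alone, camera adjusted p = 0.885). Autophagy and lysosome genes rose in 5 of 23 cases and fell in 4 (5 and 4 adjusted over the list alone, camera adjusted p = 0.861). Oxidative stress genes rose in 7 of 21 and fell in 4 (7 and 4 adjusted over the list alone, camera adjusted p = 0.298). Immediate early genes rose in 5 of 17 (3 adjusted over the list alone, camera adjusted p = 0.268).

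Cell cycle genes rose in 24 of 30 cases in wild type (27 adjusted over the list alone, median 0.49), with the mitotic genes Cdc20 and Birc5 up by 1.31 and 1.42. Interferon response genes rose in 4 of 16 (4 adjusted over the list alone, median 0.19). Their camera adjusted p values were 8.2e-12 and 0.011, and adjusted p = 0.202 and 0.432 with an estimated correlation; 2 of 32 other settings ended the interferon call.

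Over all features, 3940 of 11058 passed in wild type (2066 up and 1874 down, 4914 at an unadjusted p under 0.05), 74 of them up and 21 down by at least 2-fold, and the groups did not overlap for 3512. With median centring in place of loess 8.72% of calls were upward against 52.4%, the median of all features moved from 0.0014 to -0.19, and the calls of Col1a1 (0.70, SE 0.15, adjusted p = 0.00063) and Pdia3 ended while Acta1, Col3a1, Myh6 and Atp2a2 moved by over 1.5 times. Without the 3 arrays with high Myl7, 2540 features passed. That fit lacked wild-type sham replicates 1 and 3, and no other pair of wild-type sham arrays was left out for comparison. How much of the fall comes from the smaller group alone cannot be told.

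TAB against sham in CHIP-/- asks for the response to pressure overload when CHIP is absent. Postn rose by 4.67 (SE 0.33, adjusted p = 2.8e-10), from -3.68 ± 0.24 (SD, n = 4) to 0.99 ± 0.26 (n = 4), and Col3a1 by 3.29 (SE 0.22, adjusted p = 1.6e-10). Nmrk2 rose by 4.36 (SE 0.26, adjusted p = 3.2e-11), Serpinb1a, an inhibitor of leukocyte proteases, by 3.94 (SE 0.30, adjusted p = 5.2e-10), Cnn1 8.58-fold (log2 SE 0.18), the collagen gene Col8a1 by 3.01 (SE 0.23) and Timp1 by 2.89 (SE 0.21; its 3 probes all passed, from 1.32 to 2.89). Nppb rose by 2.73 (SE 0.16), Nppa by at least 2.87 (a lower bound, since its probe was saturated on 3 of the 4 CHIP-/- TAB arrays, with its other probe at 3.34), Myh7 by 2.10, Col1a1 by 1.94 (other probe 0.87, also past) and Acta1 by 1.52, while Atp2a2 fell by 0.90 (3 probes, all past, from -1.50 to -0.90) and Myh6 by 0.77. The largest falls were those of Ift81, Ano10, Gdap10 and the carboxylesterase gene Ces1d, by 2.29, 2.21, 2.15 and 2.02, followed by the muscle ribosomal protein gene Rpl3l, Rnf207, Hrc and Yipf7, by 1.84, 1.81, 1.81 and 1.70. After TAB, Rnf207 was well above background on only 2 of the 4 CHIP-/- arrays and Ces1d on 3, so background limits the exact size of their falls and their place in this order.

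Hypertrophy markers rose in 17 of 20 cases in CHIP-/- (17 adjusted over the list alone, median 1.21), and calcium handling and ion channel genes fell in 14 of 20 (15 adjusted over the list alone, median -0.62), with Pln down by 1.24. Extracellular matrix genes rose in 54 of 55 cases (54 adjusted over the list alone, median 1.39), with Serpinh1 up by 1.77 and Sparc by 1.70. Macrophage and monocyte markers rose in 20 of 21 (20 adjusted over the list alone, median 0.80), with Lyz2 up by 1.64 and Adgre1, which encodes F4/80, by 1.24. The camera test returned adjusted p = 4.9e-10, 1.2e-06, 7.8e-27 and 4.8e-12 for these lists, and for all 4 adjusted p = 0.137 with an estimated correlation. Fibroblast markers rose in 9 of 15 cases and fell in 2 (10 and 3 adjusted over the list alone), with Lum up by 1.79 and Vim by 1.77. In the camera test it had adjusted p = 0.00062, and adjusted p = 0.241 with an estimated correlation. Immediate early genes rose in 12 of 17 and fell in 1 (12 and 1 adjusted over the list alone). By camera the list had adjusted p = 0.0058, and adjusted p = 0.243 with an estimated correlation. Endothelial markers rose in 4 of 16 cases and fell in 2 (4 and 2 adjusted over the list alone, camera adjusted p = 0.626), and smooth muscle and pericyte markers rose in 8 of 13 and fell in 3 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0523).

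In CHIP-/-, fatty acid oxidation genes fell in 30 of 31 cases (30 adjusted over the list alone, median -0.87), with Acadm down by 1.34, Acsl1, a fatty acyl-CoA synthetase, by 1.20 and Hadhb by 1.16. Tricarboxylic acid cycle genes fell in 18 of 18 (18 adjusted over the list alone, median -0.79), with Sdha down by 0.96 and Pdhb by 0.94. AMPK subunits and energy regulators fell in 14 of 26 cases and rose in 3 (14 and 4 adjusted over the list alone), with Ppargc1a, the PGC-1alpha coactivator gene, down by 0.92 and Acacb by 0.95. Camera gave adjusted p = 8.9e-17, 5.9e-14 and 0.0028 for these lists, and for all 3 adjusted p = 0.137 with an estimated correlation. Oxidative phosphorylation genes fell in 47 of 59 cases (49 adjusted over the list alone, median -0.43), with the complex I genes Ndufs1 and Ndufv1 down by 0.86 and 0.72. Camera returned adjusted p = 4.5e-13, and adjusted p = 0.339 with an estimated correlation. Glycolysis genes rose in 8 of 20 cases and fell in 7 (8 and 8 adjusted over the list alone); the median was 0.05, the mean -0.08 and the test pointed down with adjusted p = 0.921.

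Endoplasmic reticulum stress genes rose in 12 of 24 cases and fell in 4 in CHIP-/- (12 and 4 adjusted over the list alone), with Pdia3 up by 0.90 and Herpud1, which acts in the degradation of misfolded proteins, down by 1.49. This list had a camera adjusted p = 0.029, and adjusted p = 0.244 with an estimated correlation, a call that 3 of 32 other settings ended. Its median was 0.20, and -0.08 to 0.29 over those 32 settings. Chaperones rose in 6 of 38 cases and fell in 11 (6 and 11 adjusted over the list alone, camera adjusted p = 0.659), with a median of 0.04, a mean of 0.01 and a test that pointed down; Fkbp4 fell by 1.17. Muscle ubiquitin ligases fell in 7 of 17 cases and rose in 3 (7 and 3 adjusted over the list alone, camera adjusted p = 0.072), with Trim63 down by 0.81 and Fbxo32 by 0.53. Proteasome subunits fell in 11 of 33 cases and rose in 4 (11 and 4 adjusted over the list alone, camera adjusted p = 0.092). Autophagy and lysosome genes rose in 8 of 23 and fell in 4 (8 and 6 adjusted over the list alone, camera adjusted p = 0.669), with a median of -0.0071 and a mean of 0.05. Oxidative stress genes rose in 5 of 21 and fell in 7 (5 and 7 adjusted over the list alone, camera adjusted p = 0.787), with a median of -0.06 and a mean of 0.0072 while the test pointed down. The glutathione peroxidase genes Gpx1 and Gpx3 rose by 0.85 and 1.32 and the transferase gene Gstm1 fell by 1.11.

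Cell cycle genes rose in 26 of 30 cases in CHIP-/- (28 adjusted over the list alone, median 0.61), with Mki67, Birc5 and Tyms up by 1.81, 1.62 and 1.37. Interferon response genes rose in 7 of 16 (7 adjusted over the list alone, median 0.18), with Isg15 up by 0.57 (well above background on 3 of the 4 sham arrays). Camera adjusted p values were 1.2e-10 and 0.025, and adjusted p = 0.19 and 0.463 with an estimated correlation; 3 of 32 other settings ended the interferon call. Cell cycle genes did not differ between the genotypes after TAB (0 of 30, 0 adjusted over the list alone, camera adjusted p = 0.739) or in the interaction (0 of 30, 0 adjusted over the list alone, camera adjusted p = 0.275).

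Over all features, 5214 of 11058 passed in CHIP-/- (2656 up and 2558 down, 5892 at an unadjusted p under 0.05), 210 of them up and 118 down by at least 2-fold, and the groups did not overlap for 4693. With median centring in place of loess 12.3% of calls were upward against 50.9%, and the median of all features moved from -0.005 to -0.22; in the heart channel alone 38.0% were upward.

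**Figure D2:**
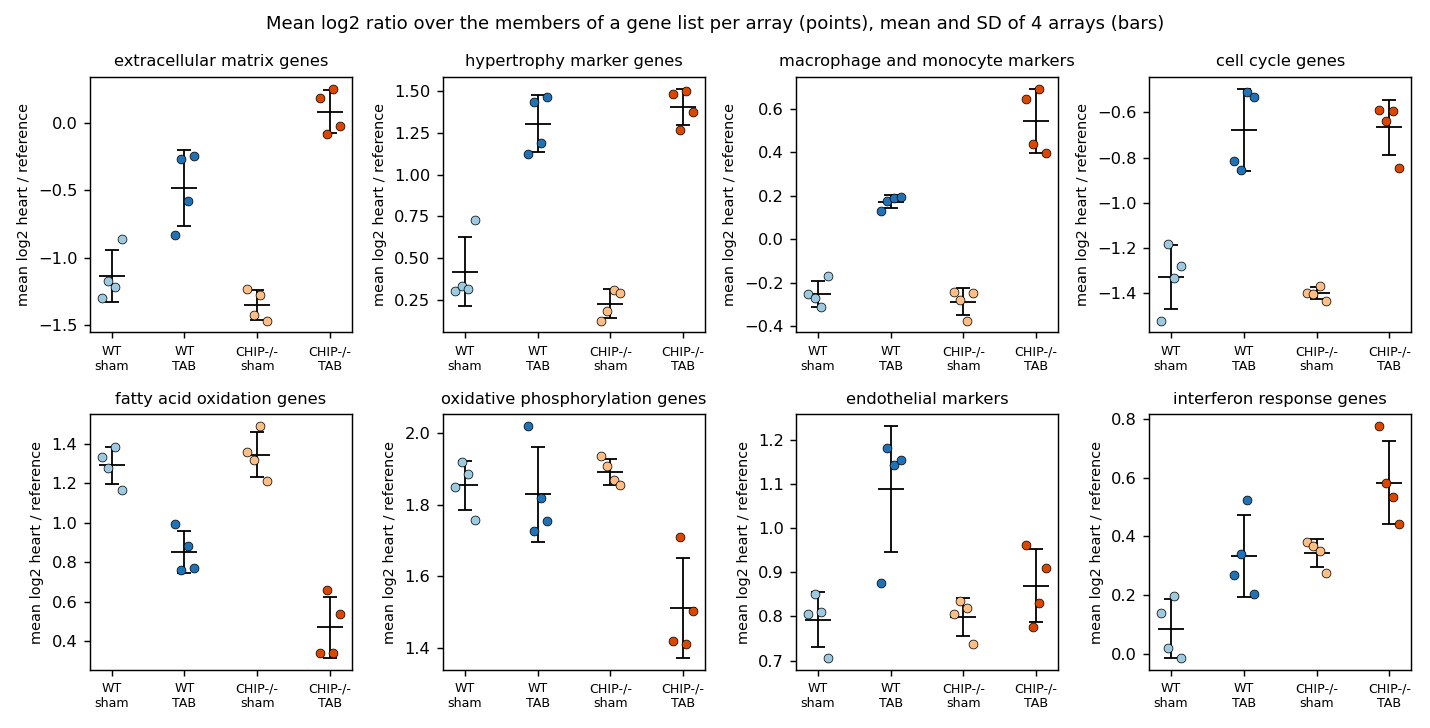
Mean log2 ratio of heart over reference RNA over the measured members of 8 gene lists (vertical axis), with 1 point per array, grouped by genotype and surgery (horizontal axis), and bars for the group mean and SD (n = 4). The mean of the extracellular matrix list lay between -0.08 and 0.25 in CHIP-/- TAB and between -0.84 and -0.25 in wild-type TAB.

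The responses of the 2 genotypes to TAB were set against each other across genes, which are not independent replicates. They correlated with r = 0.83 and rho = 0.79 (two-sided exact permutation p = 0.0286 over the CHIP-/- arrays, the smallest possible with 70 assignments). Without the 3 arrays with Y-linked signal the correlation was 0.84 with exact permutation p = 0.0667, the smallest possible there. Of the features, 1652 rose in both genotypes and 1442 fell in both, where independent calls would share 496 and 434, while 19 rose in wild type and fell in CHIP-/- (478 if independent) and 8 did the reverse (450 if independent). The principal axis of the responses had a slope of 1.46 for CHIP-/- over wild type (1.36 to 1.56 with each array left out), against 1.14 for the regression of the CHIP-/- on the wild-type response, and the SD of the responses over features was 0.41 in CHIP-/- and 0.30 in wild type.

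CHIP-/- against wild type after sham asks what the loss of CHIP changes without pressure overload. Besides Stub1, 3 features passed. Ifi27, an interferon-induced gene, was higher in CHIP-/- by 0.67 (SE 0.07, adjusted p = 4.9e-06), from -0.93 ± 0.04 (SD, n = 4) to -0.26 ± 0.16 (n = 4), while its second probe was at 0.31 and did not pass. Ly6a, which encodes the surface protein Sca-1, was higher by 0.41 (SE 0.07, adjusted p = 0.014), and Nppb was lower, at -0.98 (SE 0.16, adjusted p = 0.014), while its second probe was at -1.12 and did not pass. The call of Ly6a ended without CHIP-/- sham replicate 1, 2 or 3 without the 3 arrays with Y-linked signal, and with median centring in place of loess, and its value stayed between 0.36 and 0.50. The call of Nppb ended without wild-type sham replicate 2 or CHIP-/- sham replicate 1, 2 or 3, and with the processed signals, the deposited series table or the mean of all probes, and its value stayed between -1.32 and -0.84. In all, 4 of 11058 features passed (2 up and 2 down), against 888 at an unadjusted p under 0.05 and 593 whose groups did not overlap.

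Hspa1a, the inducible Hsp70 gene, was at -2.18 (SE 0.57, adjusted p = 0.16) in CHIP-/- against wild type after sham, and did not pass; wild-type sham replicates 2 and 4 had 1.96 and 2.61 and the other 14 arrays -1.70 to 0.56. The other panel genes did not pass either: Hspb1 was at -0.37 (adjusted p = 0.25), Bag3 at -0.17 (adjusted p = 0.57), Prkaa1 and Prkaa2, the catalytic AMPK subunits, at 0.05 and -0.10, Ppargc1a at -0.06, Fbxo32 at 0.13 and Trim63 at 0.03. Among the lists, 0 of 16 interferon response genes passed over all features (5 higher adjusted over the list alone), with a median of 0.26 and 15 of 16 members above 0. Of 38 chaperones 0 passed (12 lower adjusted over the list alone, median -0.15). Of 55 extracellular matrix genes 0 (8 lower adjusted over the list alone, median -0.22). Of 21 oxidative stress genes 0 (5 higher adjusted over the list alone, median 0.15) and of 17 immediate early genes 0 (2 lower adjusted over the list alone, median -0.15). Under camera, adjusted p = 9.8e-11, 1.3e-08, 9.8e-11, 6.5e-06 and 0.001 for these 5 lists, and adjusted p = 0.179, 0.358, 0.412, 0.179 and 0.362 with an estimated correlation. The median of the matrix list was -0.05 without the 3 arrays with Y-linked signal. The heat shock genes Hsph1 and Dnajb1 were, like Hspa1a, highest on wild-type sham replicates 2 (1.91 and 0.41) and 4 (1.73 and 0.92). No setting left out both arrays, so how far they carry the chaperone call is not known.

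Camera also called hypertrophy markers after sham (1 of 20 lower, 3 adjusted over the list alone, median -0.14, adjusted p = 0.00098), calcium handling genes (0 of 20, 0 adjusted over the list alone, median -0.10, adjusted p = 0.028) and fibroblast markers (0 of 15, 4 lower adjusted over the list alone, median -0.15, adjusted p = 0.013), and for each adjusted p = 0.412 with an estimated correlation. The fibroblast median was -0.0051 without the 3 arrays with Y-linked signal, where camera's direction turned (adjusted p = 0.885), and without the 3 arrays with high Myl7 the calcium handling median was 0.0071 (adjusted p = 0.886). Atrial markers were called lower (0 of 7, 1 adjusted over the list alone, median -0.35, adjusted p = 0.021), and adjusted p = 0.412 with an estimated correlation. Myl7 was high on 2 wild-type and 1 CHIP-/- sham arrays, without which the atrial call ended (median -0.0770, camera adjusted p = 0.0887). Fatty acid oxidation (0 of 31, 0 adjusted over the list alone, median 0.06, adjusted p = 0.041) and oxidative phosphorylation (0 of 59, 0 adjusted over the list alone, median 0.05, adjusted p = 0.001) were called higher, both with adjusted p = 0.81 with an estimated correlation, as were proteasome subunits (0 of 33, 0 adjusted over the list alone, median 0.04, adjusted p = 0.022), with adjusted p = 0.412 with an estimated correlation. Of 32 other settings, 12 ended or turned the call of calcium handling, 10 that of fatty acid oxidation, 8 that of atrial markers, 5 each those of fibroblast markers and proteasome subunits, 2 that of oxidative phosphorylation and 1 each those of hypertrophy markers and matrix genes. With fry 0 of the 32 lists passed. Without 1 array, the list count fell from 12 to 7 when wild-type sham replicate 4 or CHIP-/- sham replicate 2 was left out. The feature count ranged from 2 (without CHIP-/- sham replicate 1, 2 or 3) over 7, 9 and 11 (without wild-type sham replicate 1, wild-type sham replicate 4 or wild-type TAB replicate 1, and CHIP-/- sham replicate 4) to 15 (without wild-type sham replicate 3). A fit on the 8 sham arrays alone called 42 features, array weights 41, and the heart channel alone 43, of which 86.0% were higher against 50% of 4.

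CHIP-/- against wild type after TAB asks how ventricles under pressure overload differ when CHIP is absent. Serpinb1a was higher in CHIP-/- by 2.51 (SE 0.30, adjusted p = 1.2e-05), Postn by 1.73 (SE 0.33, adjusted p = 0.0013), Spp1, which encodes osteopontin, by 1.65 (SE 0.21, adjusted p = 2.6e-05) and Col3a1 by 1.37 (SE 0.22, adjusted p = 0.00032). Myl9, Cnn1, Serpinb1c and Clu, the clusterin gene, were higher by 1.36, 1.32, 1.32 and 1.24. Serpinb1c was well above background on only 2 of the 4 wild-type TAB arrays, so background limits its exact value and its place in this order. Pdk4 was lower, at -1.63 (SE 0.32, adjusted p = 0.0016), with 1.26 ± 0.69 (SD, n = 4) in wild type and -0.37 ± 0.23 (n = 4) in CHIP-/-. Depp1, the metalloproteinase inhibitor gene Timp4, Yipf7, Sult1a1, the Z-disc protein gene Myot and Tacc2 were at -1.20, -1.15, -1.03, -1.03, -1.02 and -0.99. The other probe of Yipf7 passed at -0.52, and 2 of the 3 probes of Tacc2 passed, with values from -0.99 to -0.21. Ppargc1a was at -0.94 (SE 0.09, adjusted p = 2.1e-06). Of the other panel genes, Bag3 passed at -0.25 (SE 0.08, adjusted p = 0.038), a call that ended in 12 of the settings tried, among them without wild-type TAB replicate 1 or 2 or CHIP-/- TAB replicate 1, 3 or 4, with values between -0.32 and -0.19. Hspa1a (0.26), Hspb1 (-0.09), Prkaa1 (0.08), Prkaa2 (-0.19), Fbxo32 (0.21) and Trim63 (-0.17, adjusted p = 0.057) did not pass.

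Extracellular matrix genes were higher in 36 of 55 cases in CHIP-/- after TAB (41 adjusted over the list alone, median 0.52), with Ltbp3 at 0.61 and Col1a2 at 0.81. Oxidative phosphorylation genes were lower in 53 of 59 (57 adjusted over the list alone, median -0.32), with the complex I genes Ndufs4, Ndufa8 and Ndufb2 at -0.45, -0.45 and -0.44. Fatty acid oxidation genes were lower in 21 of 31 (24 adjusted over the list alone, median -0.35), with Acsl1 at -0.66 and Cpt1b, the muscle carnitine palmitoyltransferase, at -0.49. Tricarboxylic acid cycle genes were lower in 12 of 18 (18 adjusted over the list alone, median -0.28). Macrophage and monocyte markers were higher in 14 of 21 and lower in 2 (15 and 2 adjusted over the list alone, median 0.37), with Lyz2 at 0.68, Cd52 at 0.98 and Cd163, a scavenger receptor of resident macrophages, at -0.64. Interferon response genes were higher in 5 of 16 (6 adjusted over the list alone, median 0.20, 16 of 16 above 0), with Ifit3 at 0.68. Camera gave adjusted p = 3.8e-25, 1.6e-28, 2.3e-13, 2.3e-10, 7e-11 and 1.4e-05 for these 6 lists, and for each adjusted p = 0.262 with an estimated correlation.

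Endothelial markers were lower in 4 of 16 cases after TAB (9 adjusted over the list alone, median -0.23), with Robo4 at -0.44 and the VEGF receptor genes Kdr and Flt1 at -0.48 and -0.38. The camera test gave adjusted p = 5.8e-05, and adjusted p = 0.285 with an estimated correlation, and the call of Flt1 ended with median centring. Glycolysis genes were higher in 7 of 20 and lower in 5 (11 and 5 adjusted over the list alone), with Slc2a4, the insulin-responsive glucose transporter gene, at -0.52. For this list camera gave adjusted p = 0.047, and adjusted p = 0.262 with an estimated correlation. Calcium handling genes were lower in 6 of 20 and higher in 1 (6 and 1 adjusted over the list alone), with Hrc at -0.82. In the camera test it had adjusted p = 0.034, and adjusted p = 0.459 with an estimated correlation. Fibroblast markers were higher in 3 of 15 and lower in 1 (4 and 1 adjusted over the list alone). By camera the list had adjusted p = 0.049, and adjusted p = 0.558 with an estimated correlation. Of 32 other settings, 11 ended the glycolysis call, 7 that of calcium handling and 13 that of fibroblast markers. Leaving out sham arrays, sex as a term and quantile scaling could not move the log2 differences after TAB. Those settings therefore say little about how stable the calls after TAB are. Of the hypertrophy markers 2 of 20 were higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.2). Of the chaperones 2 of 38 were higher and 4 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.0939). Proteasome subunits were lower in 2 of 33 cases (2 adjusted over the list alone, camera adjusted p = 0.0521). Autophagy and lysosome genes were higher in 5 of 23 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0908), with the cathepsin gene Ctsd at 0.52. No muscle ubiquitin ligase differed (0 of 17, 0 adjusted over the list alone, camera adjusted p = 0.978).

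Over all features, 1274 of 11058 differed between CHIP-/- and wild type after TAB (576 higher and 698 lower, 2703 at an unadjusted p under 0.05), 19 of them higher and 7 lower by at least 2-fold, and the groups did not overlap for 1431. The count was 811 without CHIP-/- TAB replicate 3 and 439 with median centring in place of loess, where 55.8% were higher against 45.2%.

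The interaction asks which responses to TAB differ between the genotypes. The matrix genes Postn and Col3a1 rose further in CHIP-/-, by 2.36 (SE 0.47, adjusted p = 0.0055) and 2.07 (SE 0.32, adjusted p = 0.00069), as did Serpinb1a by 2.57 (SE 0.42, adjusted p = 0.0013) and Col1a1 by 1.24 (SE 0.21, adjusted p = 0.0015; other probe 0.72, also past). Fndc1 was at 0.17 (adjusted p = 0.42) in wild type and rose by 1.94 in CHIP-/-, an interaction of 1.78 (SE 0.21, adjusted p = 0.00012). The responses of several genes had opposite signs. Pdk4 rose by 1.45 in wild type and fell by 0.90 in CHIP-/- (interaction -2.35, SE 0.46, adjusted p = 0.0044). Its CHIP-/- groups overlapped, with 0.43, 1.12, 1.16 and -0.62 after sham and -0.37, -0.33, -0.12 and -0.68 after TAB. Timp4 rose by 0.68 and fell by 0.95 (-1.64, SE 0.16, adjusted p = 1.1e-05). Tacc2 rose by 0.58 and fell by 0.71 (-1.29, with 2 of its 3 probes past, from -1.29 to -0.17), Myot rose by 0.60 and fell by 0.57 (-1.18), and Phlda1 fell by 0.53 and rose by 1.02 (1.54). Ppargc1a was at -0.04 (adjusted p = 0.79) in wild type and fell by 0.92 in CHIP-/- (interaction -0.88, SE 0.13, adjusted p = 0.00069). Clu, Spp1 and Nmrk2 rose further in CHIP-/- by 1.54, 1.53 and 1.52, and Yipf7, Ift81, Rbp7 and Herpud1 were at -1.08 (other probe -0.58, also past), -1.08, -1.07 and -1.05. Timp1 was at 1.31 (adjusted p = 0.011), with 1 of its 3 probes past the test and values from 0.62 to 1.31. Without the 3 arrays with Y-linked signal, a fit on 13 arrays, the calls of Postn (1.75, adjusted p = 0.0567), Clu (1.09, adjusted p = 0.151), Spp1 (1.23, adjusted p = 0.0953), Nmrk2 (1.53, adjusted p = 0.0621), Rbp7 (-0.92, adjusted p = 0.0595), Herpud1 (-0.94, adjusted p = 0.0599) and Timp1 (1.05, adjusted p = 0.119) ended. Nppb and Nppa passed at 0.90 (adjusted p = 0.024) and 1.14 (adjusted p = 0.047), which ended in 8 and 18 of the settings tried. The second probe of Nppb was at 1.01 and did not pass. For Nppb these settings include the fits without wild-type sham replicate 2 or 4, CHIP-/- sham replicate 3, wild-type TAB replicate 3 or CHIP-/- TAB replicate 3 (0.76 to 1.24 over all settings). The value for Nppa is a lower bound, since its probe was saturated on 3 of the 4 CHIP-/- TAB arrays, and its other probe passed at 1.47. For Nppa the settings include the fits without any 1 of 10 arrays (0.77 to 1.57 over all settings). Myh6 (-0.29), Myh7 (0.51), Acta1 (0.15), Atp2a2 (-0.41, adjusted p = 0.079) and Hspa1a (2.44, adjusted p = 0.081) did not pass.

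Extracellular matrix genes had a higher response in CHIP-/- in 33 of 55 cases (44 adjusted over the list alone, median 0.73), with Col1a2 at 1.06 and Ltbp3 at 0.73, and macrophage and monocyte markers in 8 of 21 (12 higher and 1 lower adjusted over the list alone, median 0.41), with Cd52 at 0.99. Camera gave adjusted p = 3.1e-32 and 2.1e-10, and for both adjusted p = 0.253 with an estimated correlation. Oxidative phosphorylation genes had a lower response in 28 of 59 cases (57 adjusted over the list alone, median -0.36), with Ndufs4 at -0.49. So did fatty acid oxidation genes in 16 of 31 (21 adjusted over the list alone, median -0.43), with Acsl1 at -0.68, and tricarboxylic acid cycle genes in 6 of 18 (14 adjusted over the list alone, median -0.31), with Pdhb at -0.45. Camera gave adjusted p = 1.2e-29, 2.2e-13 and 4e-10 for these lists, and for each adjusted p = 0.331 with an estimated correlation. The calls of Ndufs4 and Pdhb ended with median centring and without the 3 arrays with Y-linked signal.

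Camera also called 7 further lists in the interaction. Endothelial markers had a lower response in 3 of 16 cases (3 adjusted over the list alone, median -0.20, adjusted p = 0.0003), with Flt1 at -0.52 and Kdr at -0.54, and proteasome subunits in 1 of 33 (2 adjusted over the list alone, median -0.12, adjusted p = 0.0037). Fibroblast markers were higher in 4 of 15 and lower in 1 (5 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.0037), and atrial markers higher in 2 of 7 (2 adjusted over the list alone, median 0.51, adjusted p = 0.0085). Without the 3 sham arrays with high Myl7 the atrial call was kept with a median of 0.32 (adjusted p = 0.0104), but it ended without wild-type sham replicate 1 (median 0.22), and that of fibroblast markers ended without the 3 arrays with Y-linked signal (median 0.16, adjusted p = 0.133). With an estimated correlation the endothelial, proteasome, fibroblast and atrial lists had adjusted p = 0.378. Hypertrophy markers were higher in 4 of 20 and lower in 1 (4 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.0025), and adjusted p = 0.45 with an estimated correlation. Immediate early genes were higher in 1 of 17 (3 adjusted over the list alone, median 0.21, adjusted p = 0.0025), and adjusted p = 0.331 with an estimated correlation. Oxidative stress genes were higher in 2 of 21 and lower in 3 (2 and 5 adjusted over the list alone, median -0.19, adjusted p = 0.03), and adjusted p = 0.401 with an estimated correlation, a call that 9 of 32 other settings ended. Chaperones (1 of 38 higher, 0 adjusted over the list alone), AMPK subunits and energy regulators (1 of 26 higher and 4 lower, the same adjusted over the list alone) and muscle ubiquitin ligases (0 of 17, 0 adjusted over the list alone) had camera adjusted p = 0.199, 0.467 and 0.471.

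Over all features, 597 of 11058 passed in the interaction (312 up and 285 down, 2054 at an unadjusted p under 0.05), 37 up and 13 down by at least 2-fold. By the sign of the estimates alone, 231 of these were up in both genotypes and further in CHIP-/-, 161 down in both and further in CHIP-/-, 24 up less, 8 down less, and 173 of opposite sign. Features that also passed in each genotype numbered 166, 106, 8, 4 and 27. The count was 344 without wild-type sham replicate 4, 388 without CHIP-/- sham replicate 2, 355 without CHIP-/- TAB replicate 3 and 99 without the 3 arrays with Y-linked signal. It was 177 with median centring in place of loess, 305 with processed signals and 392 with no filter on dim probes. With sex as a term it was 643, 558 of them shared with the 597. The 23 other choices of 1 wild-type and 2 CHIP-/- sham arrays to leave out gave 64 to 306 (median 175), 3 of them 99 or fewer. Some of these choices also left out arrays with Y-linked signal, so how much of the fall to 99 comes from sex cannot be told. In the heart channel alone 31.8% were up against 52.3%, and with processed signals 40.3%.

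**Figure D3:**
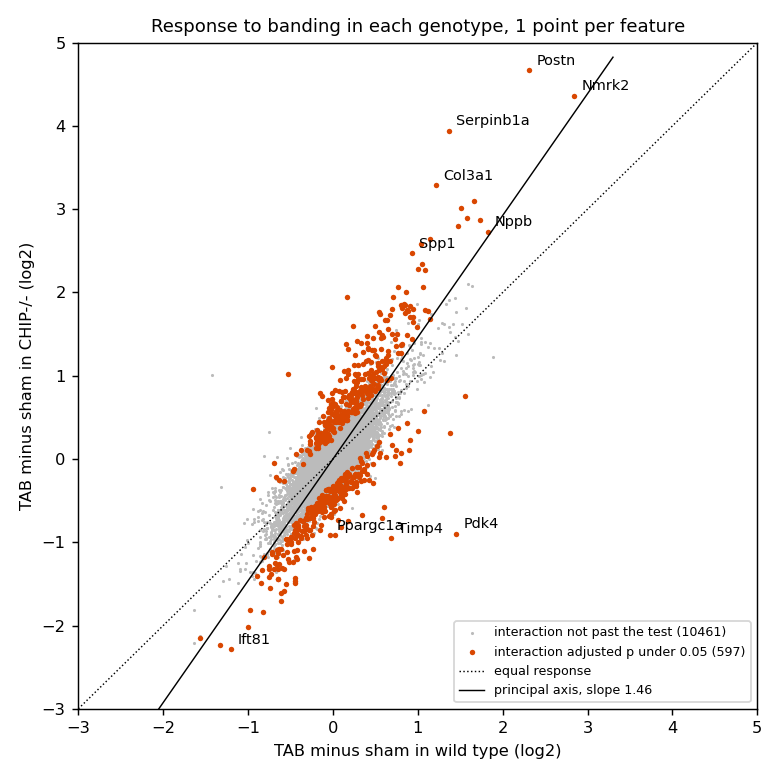
Log2 difference between TAB and sham in CHIP-/- (vertical axis) against that in wild type (horizontal axis), with 1 point per feature for 11058 features, and the 597 features past the interaction coloured. Postn lies at 2.31 and 4.67, and Pdk4 at 1.45 and -0.90.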

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

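The tests that regroup the arrays were set before the data were examined, and those that leave out Stub1 and all other tests in this part were chosen only after results were seen. The 8 arrays of each pair of groups were divided into 4 and 4 in all 35 ways, and for the interaction the genotypes were regrouped in 100 ways drawn at random, counting the real one. The real grouping gave more called features than any other in all 5 comparisons: 3940 against at most 117 for TAB in wild type, 5214 against at most 1 for TAB in CHIP-/-, 4 against at most 3 for genotype after sham, 1274 against at most 317 for genotype after TAB, and 597 against at most 559 for the interaction. For the 4 comparisons of pairs of groups, the real grouping was the only 1 of 35 to reach its count, which makes chance unlikely. For the interaction only 100 groupings were drawn, with 1 of them 38 below the real count, so chance is not excluded. Regrouping the genotypes also removes their difference after each surgery, so it does not test the interaction alone. Yet the 4 features after sham include Stub1 itself, which only the real grouping is bound to call. Other than Stub1, 3 features were called after sham against at most 3 (2 of 35 groupings had at least 3), so for these chance cannot be excluded. After TAB 1273 were called against at most 317 (1 of 35), so for these chance is unlikely. For the counts of lists past camera chance cannot be excluded in 4 comparisons: 15 lists for TAB in wild type against up to 19 (7 of 35 groupings had at least 15), 16 for TAB in CHIP-/- against up to 18 (5 of 35), 12 for genotype after TAB against up to 16 (7 of 35) and 12 for the interaction against up to 15 (14 of 100). For genotype after sham only the real grouping reached 12 lists, against at most 11 (1 of 35). The margin was 1 list, so this is weak evidence against chance. Without wild-type sham replicate 4 or CHIP-/- sham replicate 2, 7 lists passed, and 0 with fry or an estimated correlation.

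Between CHIP-/- and wild type after TAB, 36 of 55 matrix genes and 14 of 21 macrophage markers were higher (2 lower), and 53 of 59 oxidative phosphorylation genes and 4 of 16 endothelial markers were lower, although no list passed with an estimated correlation (adjusted p = 0.262, 0.262, 0.262 and 0.285). A sex difference would need Y-linked signal, which 0 of the TAB arrays had. A wild-type response enlarged by 1 factor would leave lists at 0, but with the principal axis slope of 1.46 matrix genes stayed at 0.50 (0.41 to 0.59 with each array left out), oxidative phosphorylation at -0.39 (-0.46 to -0.29) and endothelial markers at -0.36 (-0.46 to -0.28). With the regression slope of 1.14 they stayed at 0.65 (0.58 to 0.77), -0.37 (-0.43 to -0.29) and -0.25 (-0.36 to -0.19). The tests argue against sex and, for these lists, against 1 common factor. The lists were chosen after they were seen to differ between the genotypes, and the other lists were not tested for 1 factor. A slide effect stays open because each slide held 1 group, as does a genotype effect that may differ between gene groups.

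The interferon response list had medians above 0 in CHIP-/- against wild type after sham (median 0.26, 0.21 to 0.30 with each array left out) and after TAB (0.20, 0.17 to 0.27), yet 0 of 16 members passed after sham and 5 of 16 after TAB, and the list did not pass with an estimated correlation (adjusted p = 0.179 and 0.262) or with fry after sham. Strain-derived sequence that stayed linked to the disrupted gene would act on members on the chromosome that carries Stub1, yet the 14 of 16 members on other chromosomes had medians of 0.26 after sham and 0.25 after TAB, although a linked regulator could still act on them. Sex as the cause does not match the median of 0.21 after sham without the 3 arrays with Y-linked signal. Loss of CHIP could raise these genes in both states, but a slide effect stays open, and infection or housing was not tested.

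Wild-type sham replicate 4 stood above the other wild-type sham arrays in the matrix list, with a mean of -0.86 against -1.30, -1.17 and -1.22. A sex effect shared by both genotypes would raise the CHIP-/- sham arrays with Y-linked signal, which lay lower than the others by -0.18. A swap with a wild-type TAB sample would leave a TAB array at the sham level, yet the lowest TAB array reached 0.50 of the CHIP-/- response while replicate 4 reached 0.17. Atrial tissue would bring Myl7, which was -1.10 in replicate 4 against 3.82, -1.69 and 1.89 in the others. All 3 explanations are argued against, a single sample from outside the groups stays possible, and no biological explanation was tested.

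Single arrays lay far from the other 3 of their group in several measures. Wild-type sham replicate 4 was highest in the mean of the hypertrophy markers (0.73), in Postn (-1.75) and in Timp1 (-0.0341). Wild-type sham replicate 3 was lowest in the mean of the muscle ubiquitin ligases (0.64), and wild-type sham replicate 1 had the most spots well above background in the heart channel (37.7%). Wild-type TAB replicate 4 was highest in the mean of the oxidative stress genes (0.0200), replicate 1 lowest in the endothelial markers (0.88) and replicate 3 lowest in the red cell markers (-2.42). These are 8 of 212 groups of 4, and chance marks about 1 in 20 groups. Among 290 other named genes 70 of 1160 groups were marked (6.03%), 15 of them through wild-type sham replicate 4. Genes named in the text among them were Serpinb1a (-1.82), Col8a1 (1.11) and Clu (4.07) in wild-type sham replicate 4 and Myot (-1.41) and Gabarapl1 (0.20) in wild-type sham replicate 3. In the other groups they were Ly6a (2.29) and Spp1 (-4.64) in CHIP-/- sham replicate 3, Depp1 (1.33) in CHIP-/- sham replicate 4, Myl4 (-0.99, highest) in CHIP-/- sham replicate 1, Tacc2 (1.73) in wild-type TAB replicate 4, Clu (4.90) and Phlda1 (1.17) in CHIP-/- TAB replicate 1, and Sult1a1 (-1.26) and Cd163 (0.0188) in CHIP-/- TAB replicate 3.

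The test of the interaction marked 597 features as responding differently to TAB in the genotypes. The CHIP-/- response minus that of wild type was 2.57 for Serpinb1a, 2.36 for Postn, 2.07 for Col3a1, 1.78 for Fndc1, 1.54 for Clu, 1.54 for Phlda1, 1.53 for Spp1, 1.52 for Nmrk2, 1.31 for Timp1, 1.24 for Col1a1, at least 1.14 for Nppa, whose probe was saturated on 3 of the 4 CHIP-/- TAB arrays (other probe 1.47), and 0.90 for Nppb. It was -2.35 for Pdk4, -1.64 for Timp4, -1.29 for Tacc2, -1.18 for Myot, -1.08 for Yipf7, -1.08 for Ift81, -1.07 for Rbp7, -1.05 for Herpud1 and -0.88 for Ppargc1a. Other genes named in the text with a positive value were Col8a1 (1.503), Cnn1 (1.43), Myl9 (1.28), Serpinb1c (1.19, not well above background on any sham array), Col1a2 (1.06), Cd52 (0.99), Lum (0.91), Gpx3 (0.90), Serpinh1 (0.88), Sparc (0.75), Adgre1 (0.73), Ltbp3 (0.73), Lyz2 (0.70), Lyz1 (0.56), H2-DMb1 (0.56), Ctsd (0.55), Klf2 (0.42, but negative in the heart channel alone), Pdia3 (0.42) and Gpx1 (0.33). Those with a negative value were Sult1a1 (-1.02), Ces1d (-1.02), Rpl3l (-1.02), Hrc (-0.83), Fabp4 (-0.80), Ly6a (-0.70), Acsl1 (-0.68), Gdap10 (-0.59), Hadhb (-0.57), Kdr (-0.54), Cpt1b (-0.52), Flt1 (-0.52), Acadm (-0.51), Ndufs4 (-0.49), Ndufa8 (-0.49), Ndufb2 (-0.49), Gabarapl1 (-0.49), Etfa (-0.48), Slc2a4 (-0.47), Acacb (-0.46), Pdhb (-0.45), Ndufs1 (-0.43), Gstm1 (-0.40) and Ifi27 (-0.37), whose other probe was called in the opposite direction. Its list medians were 0.73 for extracellular matrix, 0.51 for atrial markers, 0.41 for macrophage markers, 0.25 for hypertrophy markers, 0.24 for fibroblast markers and 0.21 for immediate early genes, and -0.43 for fatty acid oxidation, -0.36 for oxidative phosphorylation, -0.31 for the tricarboxylic acid cycle, -0.20 for endothelial markers, -0.19 for oxidative stress and -0.12 for proteasome subunits.

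The reference channel, which the comparisons do not use on its own, should hold the same RNA on every array. On its own it gave 14 called features for TAB in wild type, 2042 for TAB in CHIP-/-, 501 for genotype after sham, 0 for genotype after TAB and 90 for the interaction. The SD of its differences over features was 0.06, 0.09, 0.08, 0.04 and 0.09, against 0.27, 0.39, 0.13, 0.18 and 0.23 in the heart channel. The counts of 2042, 501 and 90 are those of the comparisons with the CHIP-/- sham arrays. These arrays had 55 to 459 outlier spots, against 3 to 22 on the others. Their median reference signals were 50.9 to 55.2, against 56.4 to 59.1. In these comparisons the reference differences had rank correlations of -0.036, -0.015 and -0.040 with the differences of the ratio. Of the reference calls, 991, 0 and 2 were also called in the ratio, which called 5214, 4 and 597. A technical difference of the slide of the CHIP-/- sham arrays may still enter these comparisons, and its cause was not tested.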

How the results depend on the processing

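Under every alternative Stub1 kept its call for genotype after sham and after TAB, and Serpinb1a, Col3a1, Pdk4, Timp4 and Ppargc1a theirs for genotype after TAB and the interaction, and the correlation of the TAB responses stayed between 0.75 and 0.85. Over 440 pairs of a named gene and a comparison, 413 passed; 259 kept their call in all 33 settings, 150 lost it in at least 1, 13 reversed and 204 moved by over 1.5 times. In a comparison of a pair of groups, leaving out an array of another group could not move the log2 difference. Such a setting is therefore a weaker test of the call. Signal only slightly over background limits dim genes. Median centring gave 22 features for genotype after sham (4), 439 after TAB (1274) and 177 for the interaction (597); processed signals gave 305 and no filter 392 for the interaction. After sham the heart channel alone gave 43, a fit on 8 arrays 42, array weights 41 and sex as a term 14 (643 for the interaction). Without the 3 arrays with Y-linked signal 8 features passed after sham and 99 in the interaction, and the correlation was 0.84 (exact permutation p = 0.0667). For the interaction, 23 other choices of 1 wild-type and 2 CHIP-/- sham arrays gave 64 to 306 (median 175), 3 of them 99 or fewer. Without the 3 arrays with high Myl7 2540 passed for TAB in wild type and 17 after sham. A filter on both channels left 7 lists for genotype after TAB, an estimated correlation 0 lists in each of the 5 comparisons, and fry 20, 23, 0, 13 and 8. The cause was not tested.

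With each array left out, features ranged from 3408 to 4016 for TAB in wild type, 4737 to 5269 for TAB in CHIP-/-, 2 to 15 after sham, 811 to 1383 after TAB and 344 to 785 for the interaction. Stub1 ranged from -1.73 to -1.68 after sham and -1.48 to -1.25 after TAB, the correlation from 0.81 to 0.85, and lists from 14 to 16, 14 to 17, 7 to 12, 11 to 13 and 11 to 14.

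Under median centring, log2 differences reversed for TAB in CHIP-/- in Stub1 (-0.37), Psma5 (-0.22), Myh2 (-0.13), Slc4a1 (-0.13), Pck1 (-0.0740) and Tnnc2 (-0.16), and in wild type in Psma7 (-0.0785), Psma5 (-0.15), Gabarapl1 (-0.11), Ctsl (-0.0392) and Myh2 (-0.10). In the heart channel alone Klf2 turned to -0.28 for TAB in CHIP-/-, -0.0134 for genotype after TAB and -0.26 for the interaction, and Tnnc2 to -0.32 for TAB in CHIP-/-. Without the 3 arrays with Y-linked signal the direction of camera turned for fibroblast markers after sham, where the median was -0.0051. The cause was not tested.

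The replicate numbers gave no clear sign of a pairing. Of 24 same-number pairs 3 correlated over 0.1 (-0.19 to 0.19), and pairs of unlike number correlated at -0.17 to 0.26. For 7 of 16 arrays the best partner had their own number, a count that was not tested against chance. With the replicate block 3861, 5130, 5, 1178 and 504 features and 15, 16, 12, 13 and 12 lists passed, and Stub1 was -1.70 after sham and -1.34 after TAB. The slide as a block was not run, since each slide held 1 group; quantile scaling of average intensity leaves the ratios as they are.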

Other observations

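Lists outside the main themes moved with TAB as follows. Circadian clock genes fell in 7 of 11 cases in wild type (8 adjusted over the list alone, median -0.46, camera adjusted p = 0.00059, and adjusted p = 0.126 with an estimated correlation) and in 7 of 11 with 1 rise in CHIP-/- (7 and 1 adjusted over the list alone, median -0.61, camera adjusted p = 0.0067, and adjusted p = 0.149 with an estimated correlation). Dbp, a clock-controlled transcription factor gene, fell by 1.09 and 1.35, and Nr1d2, a repressor of the clock, by 0.74 and 1.01. Glucocorticoid responsive genes went both ways in wild type (2 of 11 rose and 3 fell, 3 and 4 adjusted over the list alone), with a median of 0.0069, a mean of 0.08 and a test that pointed down (camera adjusted p = 0.885). After TAB 2 of 11 were lower in CHIP-/- (4 adjusted over the list alone, median -0.24, camera adjusted p = 0.036, and adjusted p = 0.459 with an estimated correlation, a call that 6 of 32 other settings ended). Klf15, a target of the glucocorticoid receptor, fell by 0.96 in wild type and 1.41 in CHIP-/-.

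Adipocyte markers rose in 4 of 9 cases in wild type (4 adjusted over the list alone, camera adjusted p = 0.0547) and 7 of 9 in CHIP-/- (7 rose and 1 fell adjusted over the list alone, median 0.36, camera adjusted p = 0.042, and adjusted p = 0.339 with an estimated correlation, a call that 11 of 32 other settings ended), with the fatty acid carrier gene Fabp4 up by 1.55 and 0.75. Atrial markers rose in 2 of 7 cases in wild type (3 adjusted over the list alone, camera adjusted p = 0.533) and 4 of 7 in CHIP-/- (4 adjusted over the list alone, median 0.50, camera adjusted p = 0.043, and adjusted p = 0.39 with an estimated correlation, a call that 8 of 32 other settings ended). Atrial tissue in the samples is not excluded, since Myl7 was 3.82, 1.89 and 2.22 and Myl4, another atrial light chain, 0.07, -1.44 and -0.99 on 3 sham arrays (wild-type sham replicates 1 and 3, CHIP-/- sham replicate 1), against -1.99 to 0.17 and -2.76 to -1.92 on the other 13. Without those 3 arrays the median for TAB in CHIP-/- was 0.58 (camera adjusted p = 0.00079). Nerve and glia markers rose in 3 of 5 in wild type (3 adjusted over the list alone, camera adjusted p = 0.0752) and 3 of 5 in CHIP-/- (3 adjusted over the list alone, camera adjusted p = 0.113), among them Pmp22, a myelin protein gene, by 0.43 and 0.46. Skeletal muscle markers rose in 1 of 9 and fell in 2 in wild type (2 and 2 adjusted over the list alone, camera adjusted p = 0.75). Neutrophil markers rose in 1 of 4 in wild type (1 adjusted over the list alone, camera adjusted p = 0.356) and were higher in 1 of 4 in CHIP-/- after TAB (1 adjusted over the list alone, median 0.21, camera adjusted p = 0.044, and adjusted p = 0.262 with an estimated correlation, a call that 7 of 32 other settings ended), with S100a9 at 0.66. In wild type, red cell markers (0 of 5, 0 adjusted over the list alone), the lymphocyte list (0 of 1, 0 adjusted over the list alone), thymus markers (0 of 3, 0 adjusted over the list alone) and the sex-linked list (0 of 1, 0 adjusted over the list alone) had camera adjusted p values of 0.354, 0.711, 0.861 and 0.711.

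Genes of the major histocompatibility complex class I were looked at after their values were seen. They were taken by name, as B2m and all 14 features named H2-D, H2-K, H2-Q or H2-T, which include H2-DMb1 and H2-Ke6 from outside class I, with no test of the group as a whole. After TAB 11 of the 15 were higher in CHIP-/-, among them B2m, H2-K1 and H2-T23 by 0.45, 0.54 and 0.44 (adjusted p = 0.0081, 0.0016 and 0.0015). H2-Q8, H2-T10 and H2-T22 did not pass (0.43, 0.21 and 0.26, adjusted p = 0.15, 0.063 and 0.051; H2-Q8 was well above background on 1 of the 4 wild-type TAB arrays), nor did H2-Ke6 (-0.07). After sham 0 of the 15 passed (H2-K1 adjusted p = 0.091), yet 15 of 15 were above 0, and B2m, H2-K1 and H2-T23 had 0.36, 0.50 and 0.32. In the interaction 1 of 15 passed, H2-DMb1 at 0.56, so a genotype difference that appears only with TAB is not shown. The H2 genes lie on the chromosome that carries Stub1 and B2m does not, and B2m rose with TAB by 0.84 in wild type and 0.94 in CHIP-/-.

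On the 3 arrays with Y-linked signal Ddx3y was 1.42 to 1.58, against -0.73 to -0.34 on the other 13, and Eif2s3y was 1.69 to 1.78, against -1.41 to -0.83. Xist was -3.27 to -3.20 on these 3 arrays, where it was not well above background. It was -0.40 to 0.16 on the other 13, and well above background on all 13. By these genes the 3 arrays read as male and the other 13 as female, while the labels give no sex.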
